A study of Sus scrofa with 12 samples.

How the data were processed

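Digital gene expression tag profiling counts 1 short tag per transcript: complementary DNA is cut by the restriction enzyme NlaIII at CATG, and the bases that follow the cut site nearest the poly(A) tail are sequenced. The 12 libraries came from subcutaneous fat of the Jinhua pig, a Chinese native breed. Per the labels' protocols, the tissue was frozen in liquid nitrogen, RNA was extracted with Trizol, and libraries were made by Illumina's standard protocols. Each library had its own table of distinct 21-nt tags, each tag being CATG and 17 more bases. The values in the count column are raw counts of each tag, per the file headers and because they are whole numbers with a different total in every table. The TPM column holds TPM, per the file headers, which is each count scaled to a common library size. It equalled the count scaled to the library's summed count, to within 0.005. No table listed a tag with a count below 2, so an absent tag may have had a single count. The submitters' processing notes name the pig assembly Sscrofa10.2. The tool and filters behind the tables are not given in the sources used here.

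Libraries were grouped by the stage in their titles, with 3 libraries at each of 4 stages: 0 days (D0), 30 days (D30), 180 days (D180) and 7 years (Y7) after birth. No label says that the 3 libraries of a stage came from separate animals. The p-values therefore measure only the spread between these libraries, which may be technical. Summed counts per library were between 3323975 and 6037634.

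No transcript or genome sequence was used here, so tags were not matched to genes. The tags themselves were the tested features, as fixed before the data were examined for this case, and the gene lists prepared for the tissue were void and gave no result. The counts were analysed with edgeR 4.0.16 in R 4.3.3. Tags were kept by filterByExpr on the stage, which left 46967 tags with 82.4 to 92.6% of each library's counts. TMM factors were between 0.873 and 1.16. Quasi-likelihood fits (glmQLFit, glmQLFTest) used all 12 libraries with 1 mean per stage, leaving 8 residual degrees of freedom. The comparisons were D30 against D0, D180 against D30, Y7 against D180, Y7 against D0, and an F-test across the 4 stages. A tag was called at a Benjamini-Hochberg adjusted p below 0.05. The common biological coefficient of variation was 0.286. Levels in the text are in CPM, scaled by library totals without the TMM factor.

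The fit was tested on simulated data with each tag's own mean and dispersion, the libraries' totals and single counts set to 0. Of 100 tags altered 4-fold, 45 were called for D30 against D0, 47 for D180 against D30, 44 for Y7 against D180 and 45 for Y7 against D0. Of 100 tags altered 2-fold, 0, 2, 0 and 5 were called in the same order. The numbers of unaltered tags called were 2, 4, 5 and 2, or 4.26, 7.55, 10.2 and 3.85% of the calls. So few altered tags make the adjustment of p stricter than in the real data, so these numbers do not give the share of real changes that was found.

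The tags named for each comparison are the 2 that rose most and the 2 that fell most by fitted fold change, among tags with adjusted p below 0.05, a mean of at least 20 CPM in the higher stage and no overlap between the libraries of both stages. This rule was fixed before the data were examined. All tags it gave had no count in the lower stage. Their fold changes are therefore lower bounds against a floor of 3 counts in each library of that stage, which lies above the smallest listed count of 2. Bounds cover counting error only. The most abundant tag of each stage, tags restricted to 1 stage, the repeat family and pairs of similar tags were chosen after their values were seen.

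Single values per library, such as the number of distinct tags, were compared with exact permutation tests over all 15400 divisions of the 12 libraries into 4 sets of 3. The statistic was the variance between stage means, and 12 measures were adjusted together. Differences between adjacent stages used two-sided exact permutation tests of 3 against 3 libraries, which cannot give a p below 0.1. For equal depth, every library was thinned at random to 3323975 counts. Distinct tags were then those with at least 2 counts.

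Tags were also sorted by sequence. An error neighbour is a tag 1 base away from another tag with at least 50 times its count over all libraries. Adapter tags begin, after CATG, with the first 8 bases of the NlaIII tag adapter, and poly(A) tags end in at least 6 A. Members of the repeat family begin with CATGAGGTTGCGGGTTCG, the sequence at the CATG site of PRE-1, a pig short interspersed repeat derived from a tRNA. That sequence and the adapter are from background knowledge. Similar tags were paired where both had a mean of at least 20 CPM in some stage, differed at 1 base and had at least 50 counts together in every library, leaving out the 3 sorted groups and the repeat family. A library was taken to hold 1 form of a pair where the other form had at most 0.05 of their joint count, and both forms where each had at least 0.2. Other fractions were not compared. A pair was informative where at least 1 library differed from another. This definition replaced a first one after its values had been seen. The first kept the tags of all sorted groups and split all fractions into 3 classes at 0.1 and 0.9, with no gap. Both class limits were then run with and without the sorted groups.

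Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, library totals alone, other filters, a fold threshold, fits to the compared stages alone, the replicate number as a block, leaving out each library and thinning. Alternatives to the matching of tags to genes were not run. Setting single counts to 0 changes nothing, since none is listed. Further alternatives, chosen after the data were seen, left out groups of tags or libraries, set absent tags to 1 count or centred levels by GC content. Tables and figures were made with Python 3.11.15.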

Results

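Tag counts were measured in subcutaneous fat of Jinhua pigs at birth (D0), at 30 days (D30), at 180 days (D180) and at 7 years (Y7), with 3 libraries per stage, to follow expression in this tissue from birth to old age. Summed counts per library were 3991569 to 6037634 at D0, 4131235 to 4408284 at D30, 4429905 to 5317509 at D180 and 3323975 to 4395011 at Y7. Together the libraries held 793087 distinct tags. Of these, 456681 (57.6%) were listed in 1 library only, while 38273 were listed in all 12 and carried 85.5% of all counts. Of the 46967 tags with enough counts to test, 34766 (74.0%) differed across the 4 stages (edgeR quasi-likelihood F-test, adjusted p below 0.05). The labels do not say whether the libraries of a stage came from separate animals, so the tests measure the spread between libraries only.

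Libraries of a stage resembled each other more than libraries of any other stage. Spearman's rho across tested tags was 0.834 to 0.937 within stages and 0.407 to 0.709 between them, and tags are not independent replicates. The stages did not line up by age. D0 was closer to D180 (mean rho 0.683) than to D30 (0.617), and Y7 was closer to D30 (0.652) than to D180 (0.573). The lowest mean rho, 0.439, was between D0 and Y7. The first principal component, with 41.8% of the variance, placed the stages in the order D0, D180, D30, Y7. Libraries of 1 stage differed from each other by more than counting noise alone gives, with a chi-square of 3.84 to 15.8 per degree of freedom over tags, which does not tell repeat preparations of 1 RNA from separate ones.

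Of 958 pairs of tags 1 base apart, 93 changed between libraries in which of the forms were present, when fractions between these classes were not compared. The percentages for this definition are shares of these informative pairs, which were selected for differing somewhere. Libraries of different stages differed at 57.7% of the informative pairs they could be compared at, with a range of 30.6 to 72.8% over 54 library pairs. Within D0 none of 252 such comparisons differed, and within D180 none of 216. At D30, replicates 1 and 3 differed at 0 of 84 pairs, while replicate 2 differed from them at 44.6 and 45.1%. At Y7, replicates 1 and 3 differed at 0 of 86 pairs, and replicate 2 differed from them at 21.6 and 21.9%. These counts of 0 rest on that definition, which was chosen after a first one had been seen. With the first, which compared every fraction and kept all tags, libraries differed at 17.1 to 19.1% of 257 pairs within D0, at 11.3 to 13.2% within D180 and at a mean of 45.1% between stages. Replicates 1 and 3 then differed at 12.1% of the pairs at D30 and at 15.2% at Y7. With the gap, Y7 replicate 2 was compared with replicates 1 and 3 at only 74 and 73 pairs. Over the 93 pairs, 26.9% of its fractions lay between 0.05 and 0.25 or between 0.75 and 0.95. D180 libraries had 24.7 to 29.0% there, and the other libraries 6.45 to 14.0%. Both forms exceeded 0.05 at 69.9% of pairs in Y7 replicate 2, at 71.0 to 73.1% in D180 libraries and at 39.8 to 57.0% in the others.

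**Figure D1:**
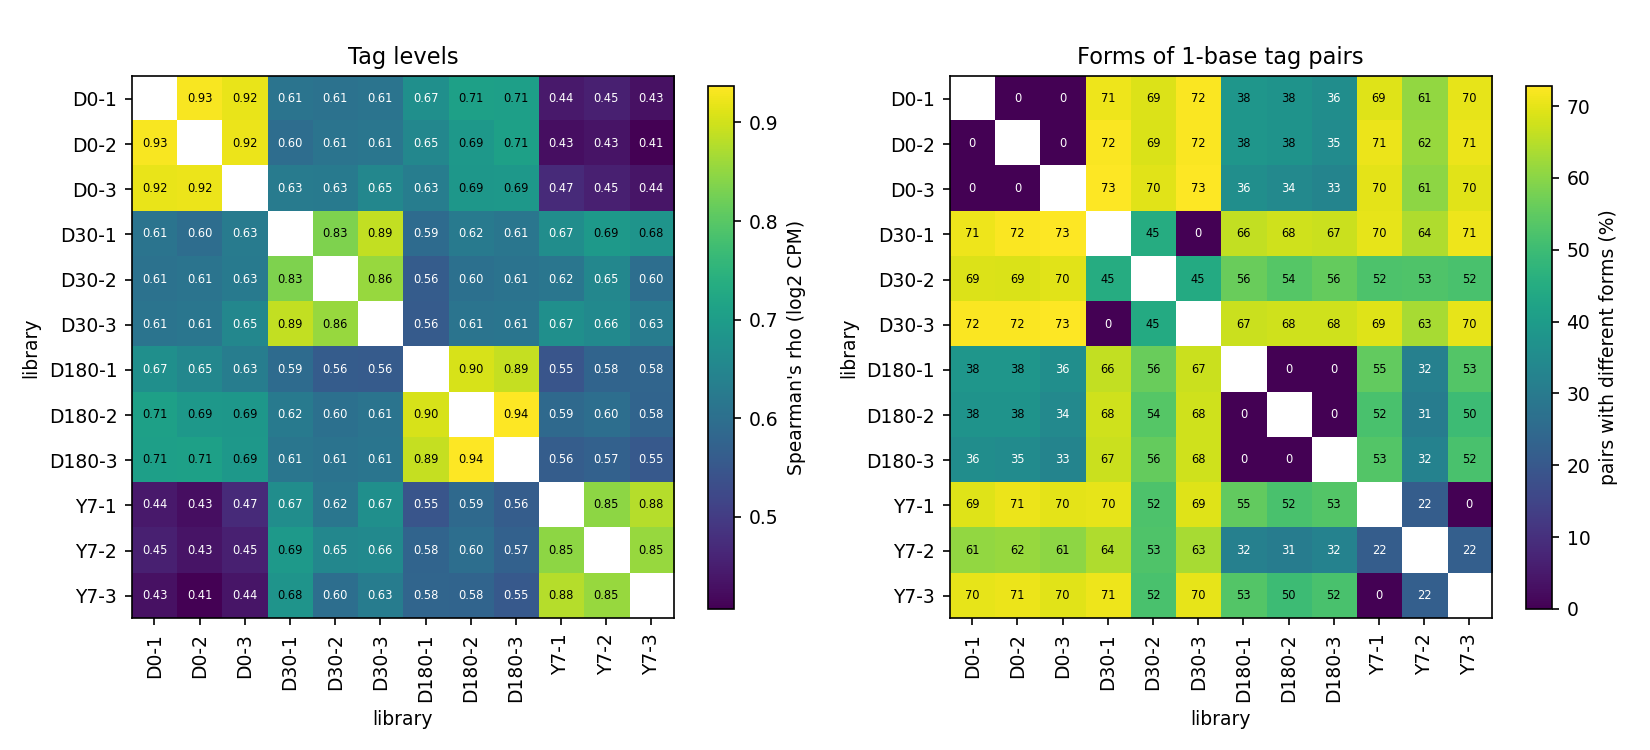
Relations between the 12 libraries, named by stage and replicate. The left map gives Spearman's rho of log2 CPM across tested tags, between 0.407 and 0.937, and the right map gives the percentage of informative 1-base tag pairs at which 2 libraries held different forms, which was 0 within D0, within D180 and between replicates 1 and 3 of D30 and of Y7 with fractions between classes left out.

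A different tag was the most abundant at each stage. CATGACCAAAAACCAAAAGTG led at D0 with 22521 ± 2920 CPM (SD, n = 3) and declined to 8669 ± 2658 at D30, 5051 ± 493 at D180 and 243 ± 18 at Y7. CATGCCAGTGGGAATGTAAAG led at D30 with 19063 ± 1526 CPM, against 4672 ± 931 at D0, 1524 ± 563 at D180 and 1149 ± 274 at Y7. CATGCCCATTGTACTTGAACT led at D180 with 21876 ± 4081 CPM and stayed among the 4 most abundant tags throughout, at 14779 ± 2098, 11910 ± 1905 and 10044 ± 480 CPM at D0, D30 and Y7. CATGACCACTTACCGGAGCCC led at Y7 with 32478 ± 4762 CPM, against 3317 ± 180 at D0, 13866 ± 1662 at D30 and 7529 ± 530 at D180. Each differed across the stages, with adjusted p from 1.21e-09 to 0.00123 in the edgeR test. Of the 100 most abundant tags of each stage, 30 were shared by all 4 stages. D0 shared 68 of its 100 with D180 and 44 with Y7.

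**Figure D2:**
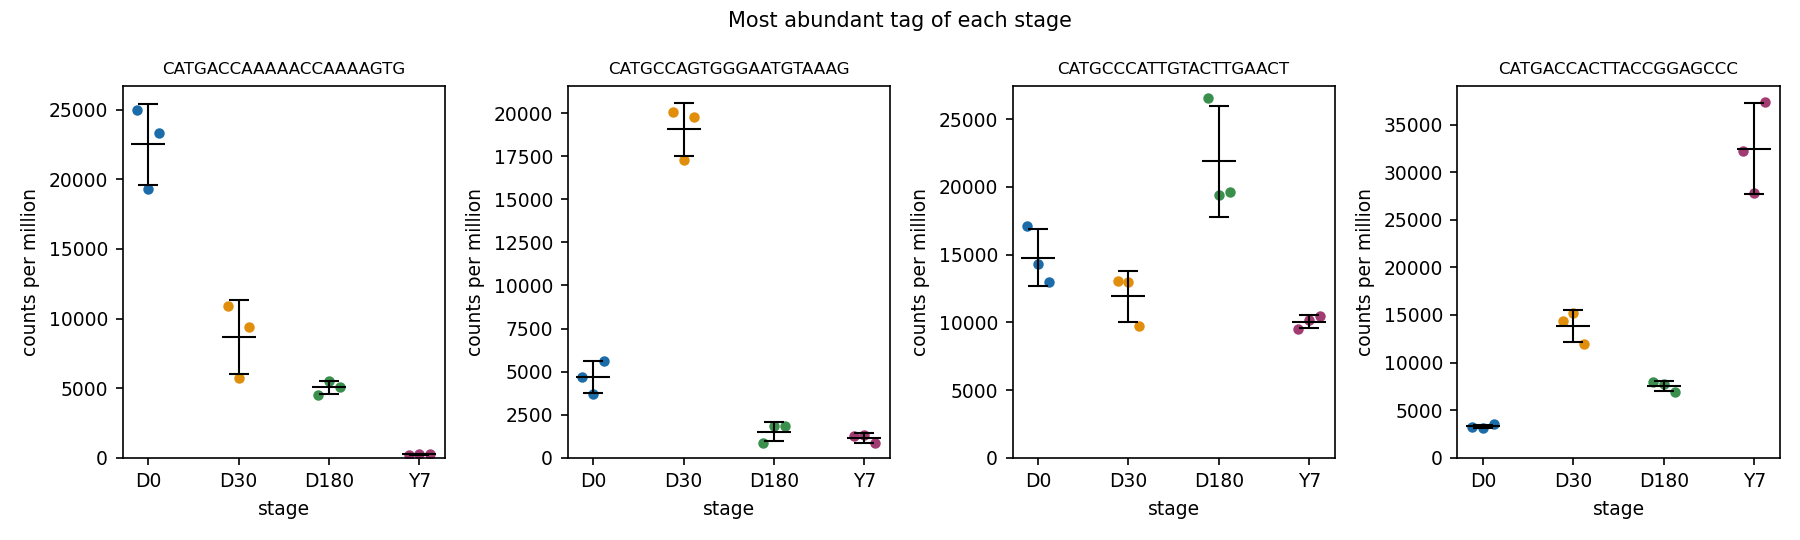
Level of the most abundant tag of each stage in CPM (vertical axis, linear from 0) by stage. Points are libraries, and bars give the mean and SD of 3 libraries. CATGACCAAAAACCAAAAGTG fell from 22521 CPM at D0 to 243 CPM at Y7, and CATGACCACTTACCGGAGCCC was highest at Y7 with 32478 CPM.

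Of the 10026 tested tags with at least 20 CPM in some stage, 9023 differed across the stages. Their highest mean lay at D0 for 2582 tags, at D30 for 1771, at D180 for 2275 and at Y7 for 2395. The lowest mean lay at Y7 for 3062 tags and at D180 for 1680. Means rose at every step with age for 545 tags and fell at every step for 573, where an equal spread over the 24 orders would give 376 each. The commonest orders were Y7, D30, D180, D0 from lowest to highest mean, with 1127 tags, and its mirror, with 1024. Tags with at least 20 CPM at 1 stage and no listed count in any library of the others numbered 87 at D0, 16 at D30, 1 at D180 and 0 at Y7. The most abundant of those at D0 was CATGGCTCATTCTGAGTGGAC.

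From D0 to D30, CATGTCAGATTTTTGTATATT rose most. It had no count at D0 and 2568 ± 297 CPM (SD, n = 3) at D30, at least 4059-fold higher (edgeR adjusted p = 8.87e-10). CATGCCGATTAAAACTGTTAA rose from no count to 525 ± 145 CPM, at least 829-fold. A partner tag that differs from it by G7A, counting from 1 at the first base of CATG, went the other way, from 65.6 ± 22.7 CPM to no count. CATGGCTCATTCTGAGTGGAC fell from 738 ± 109 CPM to no count, at least 1056-fold lower, and CATGTGCCCGACTTCTTAATC fell from 721 ± 287 CPM to no count, at least 1032-fold lower. Both were also without counts at D180 and Y7. Among the leading tags, CATGCCAGTGGGAATGTAAAG rose by 1.98 ± 0.30 (SE) on the log2 scale and CATGACCAAAAACCAAAAGTG fell by 1.44 ± 0.26. Repeat family tags rose together, 14 of 17 being called higher and 0 lower. In all, 18125 tags were called, 9132 higher and 8993 lower at D30, and 7277 of them had a fitted change of at least 4-fold. The balance depended on the setting, with 9923 higher and 8267 lower with library totals alone (median log2 fold 0.13) and 5975 higher and 7739 lower with no filter. Libraries of both stages did not overlap for 51.7% of tested tags, where chance gives 10%.

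From D30 to D180, CATGACATTAAAAGAAATATT rose from no count to 406 ± 59.8 CPM, at least 581-fold higher (edgeR adjusted p = 1.07e-09). Its partner by A17C was present at D30, at 288 ± 65.5 CPM, and reached 593 ± 66.7 CPM at D180. CATGTGAAGTAACAAACTGAT rose from no count to 236 ± 11.8 CPM, at least 338-fold, while its partner by A20G had 89.3 ± 33.6 CPM at D30 and 151 ± 21.0 at D180. CATGCTAGGACCAAAACATAT fell from 466 ± 240 CPM to no count, at least 769-fold lower, and CATGAGGACCACCCCACACCT fell from 221 ± 34.5 CPM, at least 365-fold lower. Both also had no count at D0. The leading tag of D30, CATGCCAGTGGGAATGTAAAG, fell by 3.54 ± 0.32 (SE) on the log2 scale, and that of D180, CATGCCCATTGTACTTGAACT, rose by 1.00 ± 0.26. The test called 19978 tags, 10117 higher and 9861 lower at D180. With library totals alone the balance turned, with 8874 higher and 11136 lower and a median log2 fold of -0.15. With no filter it was 9373 higher and 7406 lower. Of 153 tested adapter tags, 122 were called lower and 0 higher.

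From D180 to Y7, CATGTAGGGGAAGGAGGAGGG rose from no count to 69.4 ± 23 CPM, at least 114-fold higher (edgeR adjusted p = 7.04e-07), and CATGTAGGAGATAGAAATTTT rose from no count to 40.5 ± 24 CPM, at least 66.7-fold. The latter rested partly on Y7 replicate 1, without which its fitted log2 fold was 9.78 in place of 10.42, still called. CATGCAGACTCTTGCCACGAT fell from 66.0 ± 6.08 CPM to no count, at least 85.3-fold lower. It is an error neighbour, by G7A, of a tag that itself went from 11358 ± 1395 to 892 ± 256 CPM. At D0 and D30 that tag had 10012 ± 1310 and 12044 ± 3813 CPM, while CATGCAGACTCTTGCCACGAT had 3.68 ± 4.14 and 1.17 ± 0.27. CATGAAAGCCCAGCCATCATC fell from 37.8 ± 5.89 CPM to no count, at least 48.8-fold lower. The leading tag of Y7, CATGACCACTTACCGGAGCCC, rose by 1.92 ± 0.25 (SE) on the log2 scale, while CATGACCAAAAACCAAAAGTG fell by 4.57 ± 0.30 (adjusted p = 8.38e-08). Among abundant tags more were called lower than higher: of 374 tags with at least 500 CPM in some stage, 194 were called lower and 75 higher. Among those of 100 to 500 CPM, 747 were called lower and 405 higher. With library totals in place of TMM factors these counts were 170 and 93, and 628 and 507. In all, 22419 tags were called, 10885 higher and 11534 lower at Y7. With library totals alone the split was 14197 higher and 8774 lower, since the median log2 fold of all tested tags then lay at 0.27. With no filter it was 7726 higher and 11673 lower. Of the adapter tags, 122 of 153 were called higher, while their summed share of counts gave an exact permutation p across stages of 0.197 (adjusted p = 0.236), and the adapter sequence itself was at 18098 CPM in Y7 replicate 1 and at 768 and 615 CPM in replicates 2 and 3.

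From D0 to Y7, over the whole age range, CATGCGATTTTCCCGGTGCCG rose from no count to 156 ± 74.5 CPM, at least 246-fold higher (edgeR adjusted p = 5.45e-08). Its partner by T17C had 24 ± 13.3 CPM at D0 and 6.98 ± 12.1 at Y7, where only replicate 2 held it. CATGTGAAGTAACAAACTGAT rose from no count to 126 ± 51.8 CPM, at least 199-fold, and its A20G partner had 282 ± 78.5 CPM at D0 and 95.9 ± 24.7 at Y7. CATGCGGTTGTGTGATTCTTT fell from 982 ± 227 CPM to no count, at least 1269-fold lower, and its partner by G7T fell from 42.7 ± 8.60 CPM to no count. CATGGCTCATTCTGAGTGGAC fell at least 953-fold. CATGACCAAAAACCAAAAGTG, the leading tag of D0, fell by 6.67 ± 0.33 (SE) on the log2 scale, and CATGACCACTTACCGGAGCCC rose by 3.16 ± 0.26. Repeat family tags rose again, 16 of 17 being called higher. Of the comparisons of 2 stages this one called the most tags, 26101, with 12829 higher and 13272 lower at Y7. With library totals alone the balance turned, with 15301 higher and 10971 lower and a median log2 fold of 0.24, and with no filter it was 12562 higher and 14893 lower. Keeping only tags with at least 5 CPM in at least 3 libraries left 26624 tags to test and 16863 calls.

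The oldest stage held the most distinct tags. At an equal depth of 3323975 counts, Y7 libraries had 213361 ± 15098 distinct tags (SD, n = 3), against 118714 ± 5519 at D0, 137451 ± 9114 at D30 and 123161 ± 3539 at D180 (exact permutation p = 0.000325 across stages, adjusted p = 0.00195 over 12 measures). With at least 5 counts per tag the excess of Y7 over D180 was smaller, a ratio of 1.29 in place of 1.73. The 1000 most abundant tags of a library took 44.3 ± 0.21% of its counts at Y7 and 50.6 ± 0.98% at D0 (exact permutation p across stages = 0.0101). The share of the 10 most abundant went the other way, with 11.2 ± 1.21% at Y7, 8.85 ± 0.53% at D0, 10.8 ± 0.39% at D30 and 11.1 ± 0.47% at D180 (exact permutation p across stages = 0.0183, adjusted p = 0.0275). The repeat family made up 0.330 ± 0.054% of counts at D0, 0.948 ± 0.163% at D30, 0.586 ± 0.031% at D180 and 1.43 ± 0.33% at Y7. Its exact permutation p, 6.49e-05, is the smallest that the divisions can give. The family from the opposite strand of the same site was much rarer, with 0.0152 ± 0.0053%, 0.0116 ± 0.0031%, 0.0234 ± 0.0019% and 0.0339 ± 0.0090% of counts in the same order. Between adjacent stages, 3 libraries against 3 cannot give a p below 0.1. The repeat family and the distinct tags reached that value at each of the 3 steps.

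**Figure D3:**
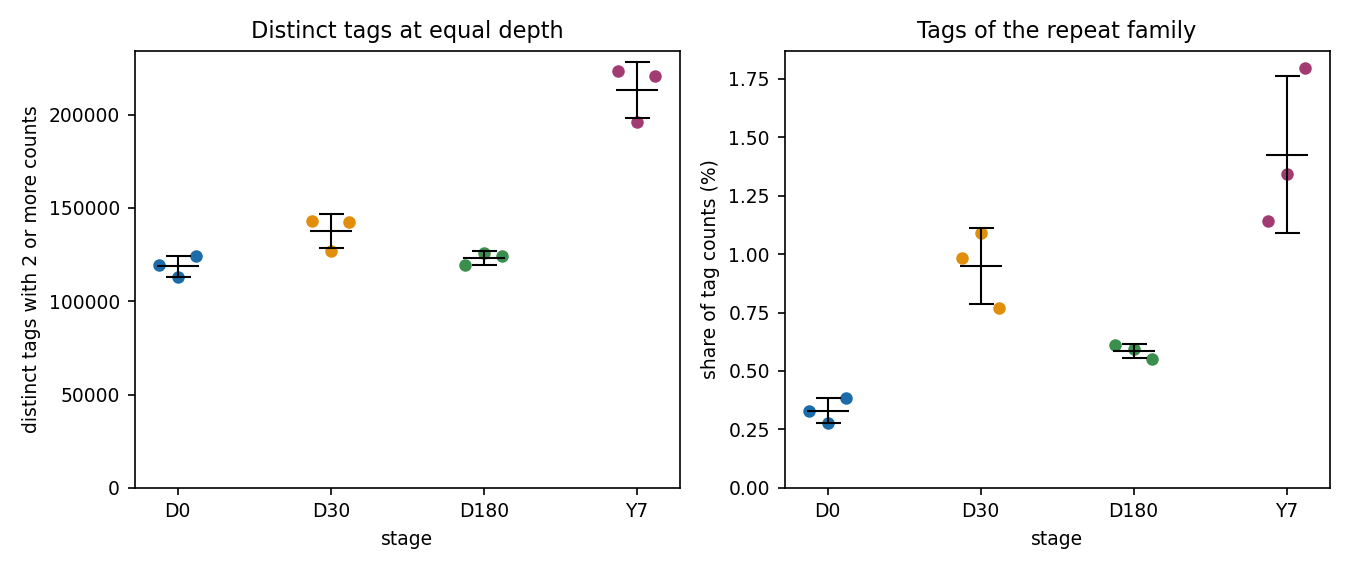
Distinct tags at 3323975 counts per library (left) and the share of counts in tags of the PRE-1 repeat family (right, percent) by stage. Points are libraries, and bars give the mean and SD of 3 libraries. Y7 stands highest in both, with 213361 distinct tags and 1.43% of counts.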

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

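Of 139 refits of the numbers of tags called, 137 stayed within 1.5 times the reported number. With only tags of at least 5 CPM in at least 3 libraries, Y7 against D0 gave 16863 calls in place of 26101 and the 4 stages gave 21889 in place of 34766, because 26624 tags were tested in place of 46967. Over the other settings the lowest and highest numbers were 13714 and 19790 for D30 against D0, 16779 and 21683 for D180 against D30, 19386 and 23973 for Y7 against D180, 22526 and 27455 for Y7 against D0, and 29862 and 43877 across stages. Leaving out each library in turn gave 14086 to 19894, 16985 to 22265, 19416 to 25651, 24533 to 30407 and 35623 to 38661 in the same order. All 442 refits of the named tags kept direction and call. These tags were picked for the largest fold changes and had no count in the lower stage, so this says little about other tags. In 5 cases the named tag was itself removed with tags that have a partner, and in 1 as an error neighbour. With the replicate number as a block the fits called 16894, 18788, 21065, 25158 and 33298 tags. Of 18 pairs of libraries with the same number in different stages, 5 had deviations correlated above 0.1. Their mean correlation was 0.0024, with a range of -0.180 to 0.130, against -0.156 to 0.235 for different numbers, so the numbers were not taken as a pairing. A shared effect of the number is not excluded, since 7 of 12 libraries agreed best with their own number. Between D0 and D30, same-number correlations were 0.0869 to 0.125 and all others were negative. The settings that left out groups of tags, left out D30 replicate 2 and Y7 replicate 2, set absent tags to 1 count or centred GC content were chosen after seeing the data. Alternatives for matching tags to genes were not run. With all libraries thinned to 3323975 counts 40163 tags were tested and 15623, 17095, 19386, 22526 and 29862 called, so depth limits how many tags can be tested.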

Other observations

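The divisions of the libraries, the test on summed pair levels and the test on partners of absent tags were set out before their results were seen; the tests on separate animals, sequencing errors, incomplete digestion, genomic DNA, GC content, sorted tags, differences between animals and alleles shared by D30 and Y7 were chosen only after the result was seen, and the genomic DNA test was reworded once after its values were seen. For each comparison of 2 stages, the 10 divisions of the 6 libraries into 3 and 3 are too few for a share below 0.05. The stages called 18125, 19978, 22419 and 26101 tags for D30 against D0, D180 against D30, Y7 against D180 and Y7 against D0. In each case 1 of 10 divisions, the real one, reached that number, and the highest of the others was 0 by edgeR, with 599 to 2877 tags at an unadjusted p below 0.05. Across the 4 stages, 1 of 100 divisions, the real one, reached 34766 tags and the highest of the others was 18652. Chance can be excluded there only for the grouping of these libraries by stage. The other divisions mix libraries of different stages, so they do not test chance differences between the animals behind the stages.

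The forms of 1-base tag pairs bear on what the 3 libraries of a stage are, and a hypothesis is that the pairs are alleles and that libraries of D0, of D180 and replicates 1 and 3 of D30 and of Y7 may each share an RNA source. Near variants of the repeat family's start were among the informative pairs, so not every pair need be alleles of 1 site. With fractions between classes left out, the libraries of D0 and of D180 differed at 0 of 468 comparisons and replicates 1 and 3 at 0, where separate animals would be expected to differ, but replicates 1 and 3 were picked by this same measure. Without that gap, and with sorted tags left out or kept, the mean was 16.6 or 18.2% within D0 and 9.89 or 12.5% within D180. It was 10.05 or 12.1% between replicates 1 and 3 of D30, 11.96 or 15.2% between those of Y7, and 47.1 or 45.1% between stages. Separate animals are therefore not excluded. The differences within D0, within D180 and between replicates 1 and 3 each involve a fraction that the gap leaves out, since none remains with it. How much of this is noise at the class limits was not tested. For a shift between 2 similar genes, the summed level was taken at the 37 pairs where D30 replicate 2 differed from replicates 1 and 3. It moved by a median of 0.414 (absolute log2, bootstrap interval 0.25 to 0.590), against 0.303 for other tags. The form that differed more moved by 8.27, but the pairs were picked for a differing form, so this contrast was built in. At the 16 such pairs of Y7 the summed level moved by 0.312 (0.131 to 0.528), against 0.333 for other tags. Both intervals lie below the 0.8 set for such a shift but reach past the 0.5 set against it. The shift is therefore not excluded. Of 346 tags with at least 20 CPM at 1 stage and no count at another, 77 (22.3%) had a partner 1 base away where absent. That partner had at least 20 CPM in any of the stages without the tag. Of 9247 other tags, 5.75% had such a partner at their lowest stage, a ratio of 3.87. The comparison is uneven, since absent tags could be checked at several stages and other tags at only 1. The ratio may therefore be too high by an unknown amount. Alleles that differ between animals may account for part of the tags that seem switched on or off, but the ratio does not settle this. Age was not tested apart from the animal.

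The order of the stages by similarity, D0 near D180 and D30 near Y7, is not that of age. With tags of middle GC content D0 was still closer to D180 than to D30, by a rho difference of 0.0662. Without adapter, repeat, poly(A) and error tags the difference was 0.0850, which argues against these as the whole cause. Count-weighted GC content was 40.3 ± 0.44% (SD, n = 3) at D0, 40.8 ± 0.51% at D180, 42.1 ± 0.95% at D30 and 43.0 ± 1.23% at Y7. It differed across stages (exact permutation p = 0.0141, adjusted p = 0.0275) and followed the order of the first principal component. Distinct tags and the repeat family share rose in the same order. A library-wide effect that goes with GC content therefore stays open as a part of the similarity. D30 replicate 2 had a mean rho of 0.845 with replicates 1 and 3, and Y7 replicate 2 had 0.848 and 0.855 with its own, against at most 0.709 between stages, which goes against differences between animals alone, but these stay open because only the pair forms mark both libraries as other animals. Pair fractions between 0.05 and 0.25 or between 0.75 and 0.95 made up 26.9% in Y7 replicate 2 and 14.0% in D30 replicate 2. The pair forms therefore mark Y7 replicate 2 less plainly. Alleles shared by D30 and Y7, as far as they show as 1-base pairs, are argued against. Without tags that have such a partner every Y7 library was closer to each D30 library than to any D180 library. The mean rho difference was 0.0673 to 0.0849. Y7 also differed from D30 at a mean of 62.8% of pairs and from D180 at 45.7%. For D0 and D180 the pair forms go with shared alleles instead. D0 differed from D180 at a mean of 36.2% of pairs and from D30 at 71.2%. Without tags that have a 1-base partner, D0 was still closer to D180 (mean rho 0.711) than to D30 (0.624). Alleles shared by D0 and D180 stay open as a part of that similarity. Alleles that show otherwise than as 1-base pairs were not tested. No label gives a library batch, and distinct adapter tags set D180 apart, with 94 to 204 against 751 or more in every other library. Their share of counts gave an exact permutation p of 0.197 across stages, though it was 0.0223 to 0.0584% at D180 and from 0.0845% upward elsewhere. Error neighbours took 0.951 and 1.11% of counts at D0 and D30, against 1.79 and 1.84% at D180 and Y7 (exact permutation p = 0.00221, adjusted p = 0.00662). The same test gave 0.143 for the share of poly(A) tags and 0.925 for that of tags with an inner CATG. Single poly(A) tags did differ by stage in edgeR. Of 1530 tested, 732 were called lower and 46 higher at Y7 than at D0. Among all 46967 tested tags these numbers were 13272 and 12829. Against D180, 418 poly(A) tags were called lower at Y7 and 37 higher. A batch that coincides with the stages therefore cannot be told apart from age.

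The excess of distinct tags at Y7 over D180 was a ratio of 1.81 without error neighbours, against 1.73 with them, which argues against sequencing errors 1 base from an abundant tag. Incomplete cutting by NlaIII would raise tags with an inner CATG, whose share of counts at Y7 was 1.03 times that at D180. Genomic DNA that gives tags from both strands alike would raise both strands of the PRE-1 site. The opposite-strand family rose by 0.0105 percentage points from D180 to Y7, 1.24% of the 0.840 points by which the repeat family rose. Its own share did rise, from 0.0234 to 0.0339%. Of its 5 tested tags, 5 were called higher at Y7 than at D30, 3 than at D0 and 0 than at D180. Genomic DNA that favours 1 strand was not tested and stays open. Age stays open as a biological explanation that was not tested, and so do a batch and the choice of animals, which coincide with the stages. Unspliced or intergenic RNA that holds the repeat is a candidate source that was not tested.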
